A study of Mus musculus with 2 samples.

How the data were processed

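ATAC-seq peak lists from 2 biological replicates of mouse kidney at embryonic day 15.5 were analysed, and no reads were used. Per the labels' protocols, DNA was fragmented by Nextera tagmentation, the library size range was 200 to 750 bp, and the kidneys of 78 embryos (replicate 1) and 62 embryos (replicate 2) were pooled. The labels number the 2 libraries as separate biological replicates, and replicate numbers were taken from them.

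The authors deposited, for each replicate, a pseudoreplicated peak list, an IDR thresholded list and an IDR ranked list, and for both replicates together pooled lists of the same kinds plus a replicated and a conservative list, per the readme headers. IDR is the irreproducible discovery rate, a measure of how far 2 rankings of the same peaks agree. The assembly is mm10, per the readme headers. The aligner, the peak caller, their versions and the calling thresholds are not given in the sources used here. How insertion sites were shifted for the transposase is also not given in the sources used here. Each peak carries a signal value in the lists the authors deposited, and what that signal is relative to is not stated, so it was used to rank, split or compare peaks within 1 list, and its log2 values were correlated between replicates in 1 alternative only. Each peak also carries a −log10 p value in the deposited lists, which was used for ranks in the ranked lists only. The ranked lists of the authors further hold a score, the −log10 of the global IDR, which was not used to filter. In the authors' ranked list of the true replicates, 2 further columns hold each replicate's −log10 p, as judged from their match to each replicate's own ranked list, with no name that tells the replicates apart. Peaks of the main lists were called per replicate, and the pooled lists were used only where named. A second pooled ranked list, whose columns matched neither replicate, was not used. With no read counts in the peak lists, the depth of each library is unknown, and no interval or detection floor was computed.

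The main list of each replicate was the pseudoreplicated list. Lines with the same or overlapping intervals (several summits per interval) were merged, keeping the highest signal and its summit. Only the 19 autosomes, X and Y were used. Chromosome names and lengths of the reference genome (GRCm38.p6) fitted the peaks on all 21 of them. Genes and transcript starts came from GENCODE release M21. A gene symbol with several entries kept the longest, which left out 27 entries and gave 21911 protein-coding genes. A promoter was the window within 1 kb of any transcript start of a protein-coding gene, and peaks outside all such windows were distal. A gene's promoter was called open when both replicates had a peak within 1 kb of any of its starts. Starts that lie far from the main start of a gene, or that it shares with a neighbour, count under this rule.

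Overlap between replicates needed 1 bp. Overlap and promoter shares were tested one-sided against 1000 circular shifts along each chromosome. The other replicate's peaks were shifted for overlap, and the promoter windows for promoter shares. Shifts can place intervals in unsequenced gaps, which lowers chance overlap. Gene lists, written with the motifs before the data were examined, were 7 of kidney cell types, 3 of other cells of the organ, 7 of other tissues, 1 of housekeeping genes and 2 of Hox genes. Of the genes named in them, 1 had no entry in the annotation under its symbol. Random lists (10000 per test) were matched in 10 bins on the CpG observed/expected ratio within 500 bp of the gene's 5' end, or on gene length. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 20 lists, at a threshold of 0.05. These tests are across genes within 2 libraries, genes are not independent replicates, and members that lie side by side share distal regions, so that p for clustered lists can be too small.

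Signal percentiles are the rank of a gene's best promoter peak among all peaks of the replicate. Named genes followed a rule set in advance. For each list these were the 3 members with the highest mean percentile over replicates, the 2 with the most distal regions, and up to 3, in alphabetical order, with no promoter peak in either replicate. The rule also took the 39 Hox genes and the 10 regions with the highest mean rank. Motifs were matched as consensus strings on both strands within 50 bp of the best summit and in windows of the same width centred 200 bp to each side. A motif was called when its ratio reached 1.2 in both replicates and was not reached by that of the reversed string, which counted as not reached where it had no match, and one with no match in the flanks was given no ratio. For reciprocal overlap and summits, p was an upper bound, since the shifted lists were compared by any overlap. Sequence matches needed 90% identity, and 80% of the region's length where so stated.

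The overlap, gene list and motif statistics were tested on simulated data, and the other statistics were not. A simulated list that kept 60.0% of the 53286 peaks of replicate 1 gave an overlap of 60.0%, and 1 of 20 sets of randomly placed intervals passed 0.05. Of 200 simulated gene lists without effect among 21000 genes, 4 passed in the open promoter test and 9 in the distal test, and all 200 lists passed in each when each promoter of the list was closed or each gene raised by 1 on the log2 scale. Smaller effects were not simulated. Passing here meant an unadjusted p below 0.05. Simulated genes were independent, and apart from the set effect their values depended on the matching variable alone. These rates therefore do not cover lists of clustered genes. A motif planted in 10% of 20000 summits raised its share by 9.78 percentage points.

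Alternatives set before the data were examined were the IDR thresholded lists, reciprocal overlap of 50%, summits inside the other interval, equal numbers of top-ranked peaks, promoters within 500 bp or 2 kb, starts of all annotated genes, the authors' replicated list, other matching variables, Fisher's exact test, flanks of 20 kb or 100 kb, medians, other motif windows and thresholds, and each replicate alone. Added after the data were seen were the basic annotation set, matching on the number of starts, and distal regions away from starts of all annotated genes. Runs of neighbouring genes for Hox paralogues 1 to 11 and, for the number of peaks only, each replicate alone were also added then. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, figures matplotlib 3.10.9, sequence searches BLAST 2.17.0 and indexing samtools 1.23.1.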

Results

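Open chromatin was mapped in mouse kidney at embryonic day 15.5, a stage at which the ureteric bud is branching and nephrons are forming from mesenchymal progenitors. The assay was ATAC-seq, in which Tn5 transposase inserts sequencing adapters into accessible DNA, so that open promoters and enhancers appear as peaks of insertions. The material came from B6NCrl mice of both sexes. There was 1 group with 2 biological replicates, pooled from 78 embryos for replicate 1 and 62 embryos for replicate 2. No treatment, other tissue or other stage was part of the series, so the comparisons were between replicates, between promoters and distal sites, and between gene lists within this tissue. The peak lists held no read counts. The sequencing depth of each library was therefore unknown, and no interval for counting error could be given. Coordinates refer to mm10 and are counted from 1.

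Most open promoters and the strongest distal sites were open in both pools of kidneys, and peaks of low signal were found again less often. Promoters of the nephron progenitor genes Itga8 and Meox2 and of the stromal genes Pbx1 and Meis1 carried a peak in each replicate. So did those of 65.0% of all protein-coding genes, and the genes named here are among the highest of their lists by promoter signal. Replicate 1 had 53286 peaks covering 1.21% of the main chromosomes, and replicate 2 had 62602 peaks covering 1.35%, a mean of 57944 ± 6587 peaks (SD, n = 2). Of the peaks of replicate 1, 80.2% overlapped a peak of replicate 2 by at least 1 bp, and 68.0% of the peaks of replicate 2 overlapped a peak of replicate 1. These shares are 2 directions of 1 comparison, so the SD of overlap shares is not a spread between independent measurements. The mean was 74.1% ± 8.66 (SD, n = 2), against 2.67% ± 0.304 after the other replicate's peaks had been shifted along each chromosome (one-sided permutation test with 1000 shifts, p = 0.001 in each replicate, the smallest they can give). Merging both lists gave 71849 regions, of which 41290 were present in both replicates, 10526 in replicate 1 alone and 20033 in replicate 2 alone. Among regions of both replicates, 38.0% lay at a promoter. For regions of replicate 1 alone and of replicate 2 alone, the promoter share was 11.9% and 10.3%. Peaks in the highest quintile of the authors' signal were found again in 99.8% ± 0.230 of cases, and peaks in the lowest quintile in 43.2% ± 14.1 (SD, n = 2). The stricter list of each replicate, thresholded on the irreproducible discovery rate (IDR), held 18324 and 20745 peaks.

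**Figure D1:**
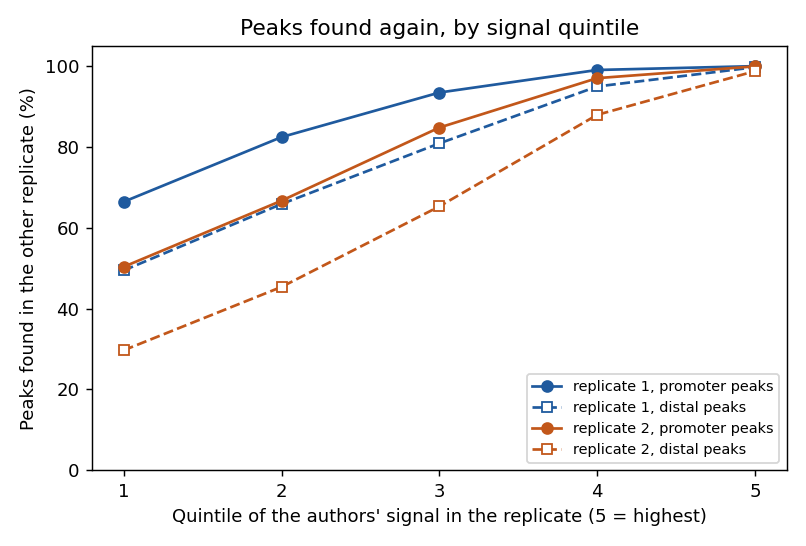
Percentage of peaks of each replicate that overlapped a peak of the other replicate (y axis), by quintile of the authors' signal within the replicate (x axis, 5 is the highest), for promoter peaks (filled circles) and distal peaks (open squares). The share rose with signal in both replicates, and the mean promoter share was above the mean distal share in each quintile, with 58.4% against 39.6% in the lowest and 98.0% against 91.5% in quintile 4.

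Without regard to signal level, signal ranks were more closely correlated across promoter regions than across distal regions. Across the 41290 regions called in both replicates, Spearman's rho of the authors' signal was 0.860. It was 0.950 across 15677 promoter regions and 0.720 across 25613 distal regions. These coefficients are across regions within 2 libraries, regions are not independent replicates, and no p was computed. In replicate 1, 8014 of 17566 promoter peaks and 2643 of 35720 distal peaks lay in the highest quintile of signal. In replicate 2 these were 8977 of 18268 and 3543 of 44334. Rho depends on the range of signal and was not computed at like signal, so the difference may reflect that range.

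The 10 regions with the highest mean signal rank over both replicates were narrow, from 247 to 586 bp, and none lay within 1 kb of a protein-coding transcript start. The first was at chromosome 2, 69355469 to 69355735, in intergenic sequence 12.9 kb from the nearest start, that of Abcb11, the bile salt export pump of hepatocytes. It was followed by a region on chromosome X at 143482934 to 143483180, 35.4 kb from Pak3, and a region on chromosome 10 at 96077546 to 96077953, 58.7 kb from Gm5426. The others lay nearest to G6pd2, Frmd4a, Tyrp1, Galc, Gm13283, Nxph1 and Hic2, at distances from 2077 bp for Gm13283 to 1766 kb for G6pd2, and all 10 were intergenic. Of these regions, 4 matched mitochondrial DNA over at least 80% of their length, and 1 other, the region near Gm13283 at chromosome 4, 88757457 to 88758042, had 14 further places in the genome at 90% identity.

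Protein-coding promoters held more peaks than shifted intervals did. Windows within 1 kb of a protein-coding transcript start made up 3.59% of the main chromosomes and held 31.1% ± 2.68 of peaks (SD, n = 2). Examples were the promoters of B2m (chromosome 2, 122147351 to 122148352 in replicate 1) and Eef1a1 (chromosome 9, 78480851 to 78482405), the translation elongation factor gene. After these windows had been shifted along each chromosome, 4.85% ± 0.0376 of peaks fell in them, a 6.41 ± 0.502-fold difference (one-sided permutation test with 1000 shifts, p = 0.001 in each replicate, the smallest they can give). Of the remaining peaks, summits in introns made up 30.0% ± 1.13 of all peaks, intergenic summits 36.0% ± 1.48, coding exons 1.31% ± 0.0332 and untranslated regions 1.23% ± 0.0249 (SD, n = 2). Among the stricter IDR thresholded peaks the promoter share was 61.1% ± 2.66.

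Promoter peaks were found in the other replicate more often than distal peaks. The shares were 90.8% ± 2.96 for promoter peaks and 66.8% ± 10.3 for distal peaks, a difference of 24.0 ± 7.34 percentage points (SD, n = 2). The difference was 18.8 points for peaks of replicate 1 and 29.2 points for peaks of replicate 2. Both values come from the same pair of lists, so they are 2 directions of 1 comparison and are not independent. Within quintiles of signal the difference was 18.8 ± 2.59 points in the lowest quintile, 16.0 ± 4.90 in the third and 0.726 ± 0.652 in the highest. Averaged over quintiles it was 12.2 ± 3.01 points. No test across samples was made with 2 replicates.

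Of 21911 protein-coding genes, 14253, or 65.0%, had a promoter peak in both replicates, and 6902 had none in either. The gene lists asked which cell types of the kidney, and of other organs, were represented among these open promoters. Each list was compared with 10000 random lists of the same size matched on promoter CpG content (two-sided permutation test, Benjamini-Hochberg adjustment over 20 lists). The smallest p that this test can give is 0.0002. Signal percentiles given below are among all peaks of a replicate. In the highest quintile lay 8014 of 17566 promoter peaks of replicate 1 and 8977 of 18268 of replicate 2, so high percentiles are common among promoters.

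Among the 7 kidney lists, renal stroma had more open promoters than matched genes, with 19 of 21 members open (90.5%) against 59.5% ± 8.46 in matched lists (adjusted permutation p = 0.0048). Within it, Pbx1, a homeodomain factor of the stroma, had its best promoter peak at chromosome 1, 168431930 to 168432892 in replicate 1, at a signal percentile of 97.2 ± 1.48. The collagen gene Col1a2 followed at 86.3 ± 3.17 and the homeodomain gene Meis1 at 83.5 ± 0.442 (SD, n = 2). Ren1, the renin gene, had no promoter peak in either replicate. The ureteric bud and collecting duct list had 17 of 18 promoters open against 81.5% ± 7.73 expected (adjusted permutation p = 0.27). Calb1, the calcium-binding protein calbindin of the ureteric tree and distal tubule, stood at percentile 98.9 ± 0.015 (chromosome 4, 15880958 to 15881732), and the ETS factor gene Etv5 and the collecting duct regulator Gata3 at 96.3 ± 0.509 and 88.7 ± 1.48. Aqp2, the vasopressin-regulated water channel, had no promoter peak in either replicate.

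In the nephron progenitor list, 15 of 18 promoters were open against 89.0% ± 7.14 expected (adjusted permutation p = 0.79). Meox2, the transcriptional coactivator gene Cited1 and the integrin gene Itga8 had the highest percentiles, at 89.0 ± 1.48, 85.1 ± 5.82 and 85.0 ± 2.80 (SD, n = 2). Meox1 lacked a promoter peak in both replicates. Of the pretubular aggregate and renal vesicle list, which holds genes of the first epithelial stages of the nephron, 13 of 14 were open against 88.7% ± 6.95 (adjusted permutation p = 1). The cadherin gene Cdh6, the Wnt antagonist gene Dkk1 and the nephric transcription factor gene Pax8 had percentiles of 86.2 ± 0.925, 81.7 ± 0.285 and 81.3 ± 5.23, and Fgf8 had no peak. Podocyte promoters were open in 13 of 15 cases against 85.0% ± 6.50 (adjusted permutation p = 1), led by Cd2ap at 94.0 ± 2.28, Magi2 at 91.9 ± 0.278 and Efnb2 at 86.6 ± 2.26. For Magi2 the best peak of each replicate lay at a different start of the gene.

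Genes of the mature tubule were mixed. Proximal tubule promoters were open in 12 of 17 cases against 51.4% ± 9.93 (adjusted permutation p = 0.2), with the endocytic receptor gene Lrp2 at percentile 81.6 ± 7.74, Fut9 at 76.6 ± 1.98 and the fatty acid transporter gene Slc27a2 at 73.5 ± 11.2 (SD, n = 2). Aldob, the phosphate transporter gene Slc34a1 and Slc5a12 had no promoter peak. Without replicate 1, 14 promoters of this list were open and the adjusted permutation p was 0.037. The loop of Henle and distal tubule list had 10 of 14 open against 54.8% ± 10.2 (adjusted permutation p = 0.3), led by Irx2 at 88.8 ± 3.07, Sim1 at 85.4 ± 1.64 and the uromodulin gene Umod at 78.0 ± 0.043. The salt transporter genes Slc12a1 and Slc12a3 lacked a peak.

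Of the other cells expected in a fetal organ, the erythroid list had more open promoters than matched genes, with 10 of 12 open against 33.6% ± 11.3 (adjusted permutation p = 0.002). The erythroid factor gene Klf1 stood at percentile 77.6 ± 3.42, the globin gene Hbb-bt at 77.3 ± 1.98 and the glycophorin gene Gypa, with a different best peak in each replicate, at 75.1 ± 3.47 (SD, n = 2), while Alas2 and Gata1, both on chromosome X, had no peak. Endothelial promoters were open in 11 of 17 cases against 62.9% ± 9.59 (adjusted permutation p = 1). Kdr, the main VEGF receptor, was at 82.8 ± 5.66, Erg at 79.0 ± 4.16 and Esam at 76.0 ± 2.82, and Pecam1 and Tek had no peak. None of the 13 macrophage and leukocyte promoters was open in either replicate, Adgre1, Aif1 and C1qa among them, against 26.4% ± 11.9 in matched lists (adjusted permutation p = 0.094, and 0.048 without replicate 1).

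Lists of other tissues included 3 with fewer open promoters than matched genes. These were germline with 1 of 10 open against 81.4% ± 8.93, pluripotency with 2 of 10 against 63.0% ± 12.97, and olfactory receptors with 6 of 1134, or 0.529%, against 13.8% ± 0.904 (adjusted permutation p = 0.0013, 0.014 and 0.0013). Dazl was the open germline promoter, at percentile 91.5 ± 1.08, while Ddx4, Hormad1 and Mael had no peak. Esrrb and Utf1 were the open pluripotency promoters, at 75.4 ± 6.84 and 45.0 ± 33.7 (SD, n = 2), the best Utf1 peak being a different one in each replicate, and Dppa3, Dppa5a and Fgf4 had none. Olfr94 had the highest percentile of the olfactory receptors, at 83.7 ± 1.44, followed by Olfr658 and Olfr15, and 1121 receptors, such as Olfr1, Olfr10 and Olfr1000, had no promoter peak in either replicate. The heart and skeletal muscle list had 3 of 15 open against 43.1% ± 10.7 (adjusted permutation p = 0.14), with Ryr2 at 89.4 ± 4.84, Ckm, with a different best peak in each replicate, at 34.5 ± 4.05 and Myog at 19.2 ± 9.49, and no peak at Acta1, Myf5 or Myh6. Liver promoters were open in 4 of 13 cases against 37.5% ± 12.3 (adjusted permutation p = 0.98), among them Apoh, Fga and Apob but not Ahsg, Alb or Ambp. Neuronal promoters were open in 9 of 17 cases against 68.8% ± 8.49 (adjusted permutation p = 0.23), with Syt1 at 98.4 ± 0.477, Elavl4 at 93.9 ± 1.85 and Snap25 at 93.2 ± 0.182, and no peak at Elavl3 or Neurod6. Adrenal and gonad steroid cell promoters were open in 4 of 11 cases against 21.5% ± 11.97 (adjusted permutation p = 0.54), Inha, Gata4 and Star among them and Cyp11a1, Cyp11b1 and Cyp17a1 not. All 15 housekeeping promoters were open against 85.0% ± 7.05 (adjusted permutation p = 0.14), with B2m, Sdha and Eef1a1 at 97.1 ± 0.0890, 96.5 ± 0.455 and 96.2 ± 1.03.

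The germline and olfactory receptor calls held under each of the 10 alternatives tried. With IDR thresholded peaks, renal stroma (38.1% open) and erythroid genes (16.7%) fell below their matched lists and lost their calls (adjusted permutation p = 0.71 and 0.96; over alternatives, 0.0013 to 0.71 and 0.0013 to 0.96). Endothelial genes, with 17.6% open in those peaks, had fewer open promoters than matched genes (adjusted permutation p = 0.019, over alternatives 0.019 to 1). Matching on gene length instead of CpG content ended the renal stroma, erythroid and pluripotency calls (adjusted permutation p = 0.1, 0.093 and 0.093). Pluripotency also lost its call with the authors' replicated list (adjusted permutation p = 0.12, over alternatives 0.008 to 0.12). The erythroid list lost its call in Fisher's exact test against all other genes, without matching on CpG content (adjusted p = 0.3). Macrophage and leukocyte genes had fewer open promoters than comparison genes under 5 alternatives, among them matching on gene length (adjusted permutation p = 0.0013, over alternatives 1.2e-05, in Fisher's exact test, to 0.38). Proximal tubule genes had more with the authors' replicated list and within 2 kb (adjusted permutation p = 0.003 and 0.027, over alternatives 0.003 to 0.99). With matching on gene length, ureteric bud, pretubular and housekeeping genes had more and muscle genes fewer (adjusted permutation p = 0.027, 0.041, 0.0024 and 0.035). Fisher's exact test, again without matching, also gave more for ureteric bud and housekeeping genes and fewer for muscle and liver genes (adjusted p = 0.017, 0.0082, 0.0027 and 0.036). The basic annotation set gave fewer for neuronal and muscle genes (adjusted permutation p = 0.03 and 0.031).

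**Figure D2:**
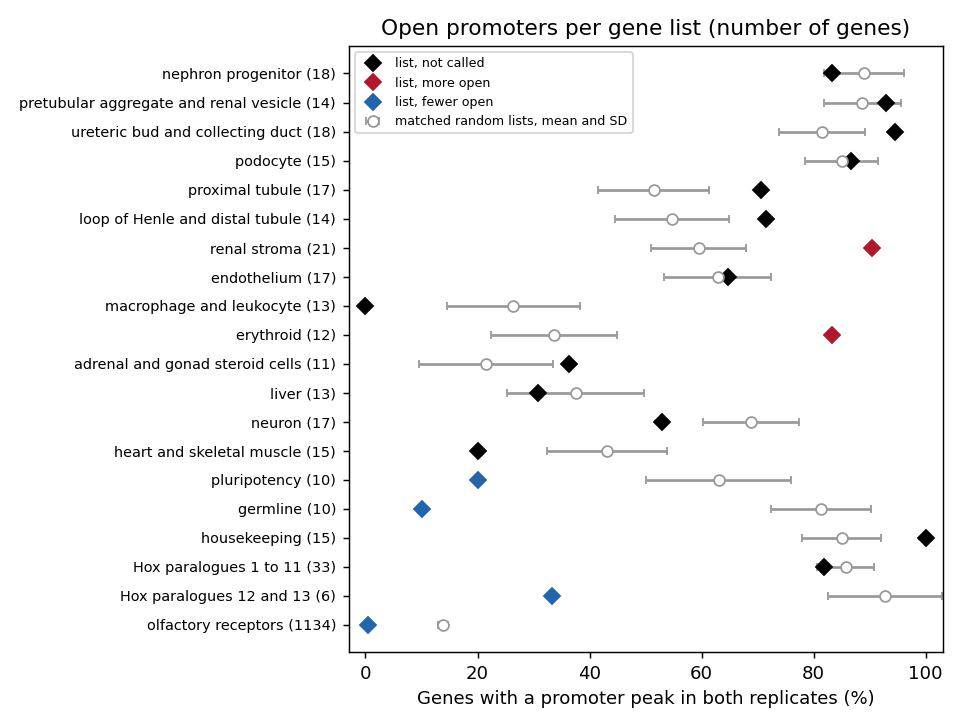
Percentage of genes of each list with a promoter peak in both replicates (x axis; diamonds) for the 20 lists (y axis, number of genes in brackets), beside the mean and SD of 10000 random lists matched on promoter CpG content (open circles with bars). Renal stroma (90.5%) and erythroid genes (83.3%) lie to the right of their matched lists, and pluripotency, germline, Hox paralogues 12 and 13 and olfactory receptor genes to the left.

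Hox genes, which pattern the body axis in 4 clusters, had open promoters along most of each cluster. Of 39 Hox genes, 29 had a promoter peak in both replicates, 4 in 1 replicate and 6 in neither. In the Hoxa cluster on chromosome 6, 8 of 11 were open, namely Hoxa1, Hoxa3, Hoxa4, Hoxa5, Hoxa7, Hoxa9, Hoxa10 and Hoxa11. In the Hoxb cluster on chromosome 11, 7 of 10 were open, which were Hoxb1, Hoxb2, Hoxb3, Hoxb4, Hoxb6, Hoxb7 and Hoxb9. The Hoxc cluster on chromosome 15 had 6 of 9 open, which were Hoxc4, Hoxc5, Hoxc6, Hoxc10, Hoxc11 and Hoxc13, and the Hoxd cluster on chromosome 2 had 8 of 9 open, all but Hoxd12. Hoxd10 had the highest signal percentile, at 83.7 ± 4.51 (SD, n = 2), followed by Hoxb7, a gene of the ureteric bud, at 80.1 ± 5.33, Hoxc13 at 76.6 ± 3.25 and Hoxc4 at 75.4 ± 8.76. Hoxc5 and Hoxc10 shared 1 peak, since an annotated Hoxc5 transcript starts at Hoxc10. No promoter peak was called in either replicate at Hoxb5, Hoxb8, Hoxb13, Hoxc8, Hoxc9 or Hoxc12. Of the paralogues 1 to 11, 27 of 33 were open against 85.7% ± 5.15 in matched lists (adjusted permutation p = 0.79). With IDR thresholded peaks they had fewer open promoters than matched genes (36.4%, adjusted permutation p = 0.0013), and with matching on gene length they had more (adjusted permutation p = 0.002). Of the paralogues 12 and 13, 2 of 6, Hoxc13 and Hoxd13, were open against 92.7% ± 10.1 (adjusted permutation p = 0.0013). The latter call rested on replicate 1, in which Hoxa13 and Hoxd12 had no peak, and without replicate 1 the adjusted permutation p was 0.18. It also ended with the authors' replicated list (adjusted permutation p = 0.12), with matching on gene length (1) and in Fisher's exact test against all other genes (0.26), a range of 0.0013 to 1 over alternatives.

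**Figure D3:**
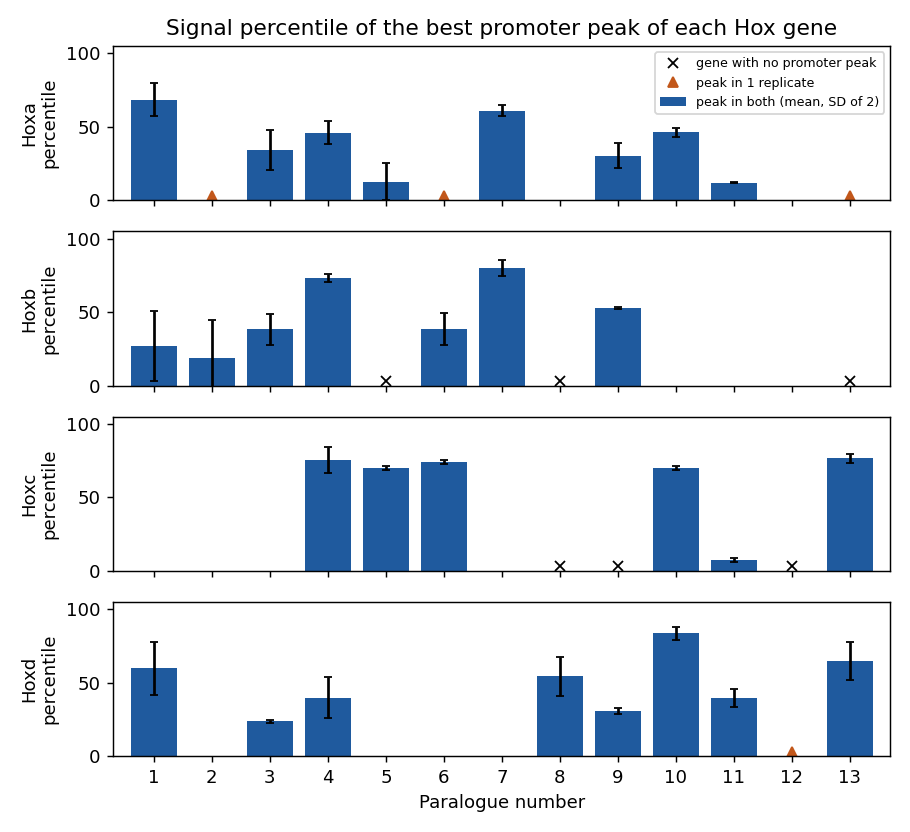
Signal percentile of the best promoter peak (y axis, percent of the replicate's peaks at or below it) by paralogue number (x axis) in the Hoxa, Hoxb, Hoxc and Hoxd clusters. Bars are the mean and SD of 2 replicates for genes open in both, triangles are genes with a peak in 1 replicate and crosses are genes with none, and the highest bar is Hoxd10 at 83.7.

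Some genes of the developing kidney, such as Pax8 and Meis2, had more distal regions around them than the median gene of like length. Of 25613 distal regions present in both replicates, those within the gene body and 50 kb to each side were counted per gene, and each list was compared with 10000 random lists matched on gene length (two-sided permutation test, Benjamini-Hochberg adjustment over 20 lists). The median gene had 1 such region, and 7735 genes had none. Genes of like length are those in the same of the 10 length bins, and the bin of the longest genes is wide. Cdh6 (145 kb), Meis2 (203 kb), Pbx1 (313 kb) and Mecom (597 kb) share its median of 3. Length is therefore not held equal within that bin. Of the 7 kidney lists, 5 had more distal regions than matched genes, as did endothelial, housekeeping and both Hox lists, and of the 7 lists of other tissues none did. Kidney lists were not tested against the other lists.

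Pretubular aggregate and renal vesicle genes exceeded matched genes by 1.09 on the log2 scale of 1 + regions (mean 2.18 against 1.09 ± 0.25, adjusted permutation p = 0.001), with 59 regions and 12 of 14 members above the median of genes of like length. Pax8 had 10 regions and Cdh6 had 8, against medians of 1 and 3 for genes of like length. Ureteric bud and collecting duct genes exceeded matched genes by 0.90 (adjusted permutation p = 0.001), 15 of 18 members being above that median. Hoxb7 had 9 regions and the ureteric tip gene Wnt11 had 7, each against a median of 1. The count at Hoxb7 is not particular to it, since Hoxb3, Hoxb6 and Hoxb8 of the same cluster also had 9. Hoxb7 is also a member of the list of Hox paralogues 1 to 11, as are Hoxa11 and Hoxd11 of the nephron progenitor list. These lists are therefore not independent. Renal stroma exceeded matched genes by 0.83 (adjusted permutation p = 0.0016), with 17 regions at Meis2 and 14 at Pbx1 against 3. Nephron progenitor genes did so by 0.77 (adjusted permutation p = 0.002), with 8 regions at Uncx against 1 and 7 at Pax2, a regulator of nephric development, against 2. Proximal tubule genes did so by 0.58 (adjusted permutation p = 0.031), Aqp1 and Cubn having 7 regions each against 1 and 3.

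The podocyte list was 0.55 above its matched lists (adjusted permutation p = 0.053), with 7 regions each at Lmx1b and Ptpro. It passed the threshold in either replicate alone, where a region need not be present in both (adjusted permutation p = 0.012 without replicate 1 and 0.02 without replicate 2). The loop of Henle and distal tubule list was 0.29 above (adjusted permutation p = 0.34), although Mecom, whose best promoter peak differed between replicates, had 15 regions against a median of 3 and Tmem52b had 6 against 1. The endothelial list exceeded matched genes by 0.52 (adjusted permutation p = 0.047), with 6 regions each at Cdh5 and Flt1. The housekeeping list did so by 0.66 (adjusted permutation p = 0.017), with 7 regions at Ubc and 6 at Actb. Erythroid genes were 0.43 above (adjusted permutation p = 0.17, and 0.01 without replicate 1), with 5 regions at Tal1 and 4 at Hba-a1, and macrophage and leukocyte genes 0.40 above (adjusted permutation p = 0.2), with 5 regions each at Cx3cr1 and Spi1.

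Among lists of other tissues, olfactory receptors had fewer distal regions than matched genes (0.16 against 0.84 ± 0.024, adjusted permutation p = 0.001), although Olfr1423 had 6 and Olfr1367 had 5. The 214 regions counted over the receptors were 90 distinct regions. The other 6 lists lay between −0.28 for germline and 0.28 for liver relative to matched genes, with adjusted permutation p from 0.34 to 0.61. The members with most regions were Syt1 with 8 and Gad2 with 5 among neuronal genes, Ambp with 5 and Apoh with 3 among liver genes, Inha and Nr5a1 with 4 each among steroid cell genes, Tnnt2 with 4 and Myl2 with 3 among muscle genes, Nanog with 3 and Tdgf1 with 2 among pluripotency genes, and Mael with 3 and Sycp3 with 2 among germline genes.

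Hox paralogues 1 to 11 were 1.81 above matched genes on the same scale (2.68 against 0.87 ± 0.15, adjusted permutation p = 0.001), and all 33 lay above the median of genes of like length. Hoxb3, Hoxb6, Hoxb7 and Hoxb8 had 9 regions each. Because the 50 kb windows of cluster neighbours overlap, the 188 regions counted over these genes were 36 distinct regions, and p for lists of clustered genes can be too small. Against 10000 random sets of 4 runs of neighbouring genes, chosen after the data were seen, the difference was 1.56 (adjusted permutation p = 0.001). Those runs were matched on neither gene length nor spacing, so their members need not share regions to the degree that Hox genes do. This p can therefore be too small as well. Hox paralogues 12 and 13 were 0.94 above matched genes (adjusted permutation p = 0.031, and 0.063 without replicate 2), with 5 regions each at Hoxd12 and Hoxd13.

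The distal calls for ureteric bud and collecting duct, Hox paralogues 1 to 11 and olfactory receptors held under all 8 alternatives run on every list. With IDR thresholded peaks, calls ended for nephron progenitor, proximal tubule, endothelial, housekeeping and Hox 12 and 13 genes, the last of which then had 0 regions (adjusted permutation p = 0.26, 0.89, 0.37, 0.14 and 0.9). For the median instead of the mean, calls ended for nephron progenitor, pretubular, stromal, endothelial, housekeeping and Hox 12 and 13 genes (adjusted permutation p = 0.055, 0.055, 0.13, 0.14, 0.45 and 0.13). Counting within 100 kb ended those for proximal tubule, endothelial and housekeeping genes (adjusted permutation p = 0.16, 0.08 and 0.094). Within 20 kb, the housekeeping call ended and germline genes had fewer regions than matched genes (adjusted permutation p = 0.11 and 0.004). Endothelial genes also lost their call with matching on nearby starts as well as length (adjusted permutation p = 0.072). Housekeeping and Hox 12 and 13 genes did so with regions away from starts of all annotated genes (adjusted permutation p = 0.061 and 0.12). Over alternatives, adjusted permutation p ranged from 0.0008 to 0.26 for nephron progenitor, 0.0046 to 0.89 for proximal tubule, 0.0008 to 0.13 for stromal and 0.0085 to 1 for podocyte genes. Podocyte genes gained a call within 100 kb, within 20 kb and with regions away from starts of all annotated genes (adjusted permutation p = 0.0085, 0.012 and 0.043).

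Counts of distal regions at single named genes depended on the settings, with 291 of them moved by more than 1.5 times, or to or from 0, under alternatives and 329 not. The main count needs a region in both replicates, so counts from 1 replicate alone tend to be higher by construction. In replicate 2 alone, the count rose from 6 to 11 at Cdh5, from 4 to 8 at Hba-a1, from 5 to 9 at Cx3cr1, from 3 to 7 at Apoh, from 7 to 12 at Lmx1b and Pax2, from 7 to 13 at Ptpro, from 8 to 17 at Uncx, from 17 to 28 at Meis2, from 15 to 23 at Mecom, from 8 to 13 at Syt1, from 4 to 7 at Inha and Tnnt2 and from 3 to 6 at Nanog. In replicate 1 alone it rose from 14 to 23 at Pbx1, from 5 to 8 at Tal1, from 3 to 5 at Mael and from 2 to 4 at Sycp3. With IDR thresholded peaks most of these counts fell, to 0 at Cdh5, Hba-a1, Apoh, Aqp1 and Spi1 among others.

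**Figure D4:**
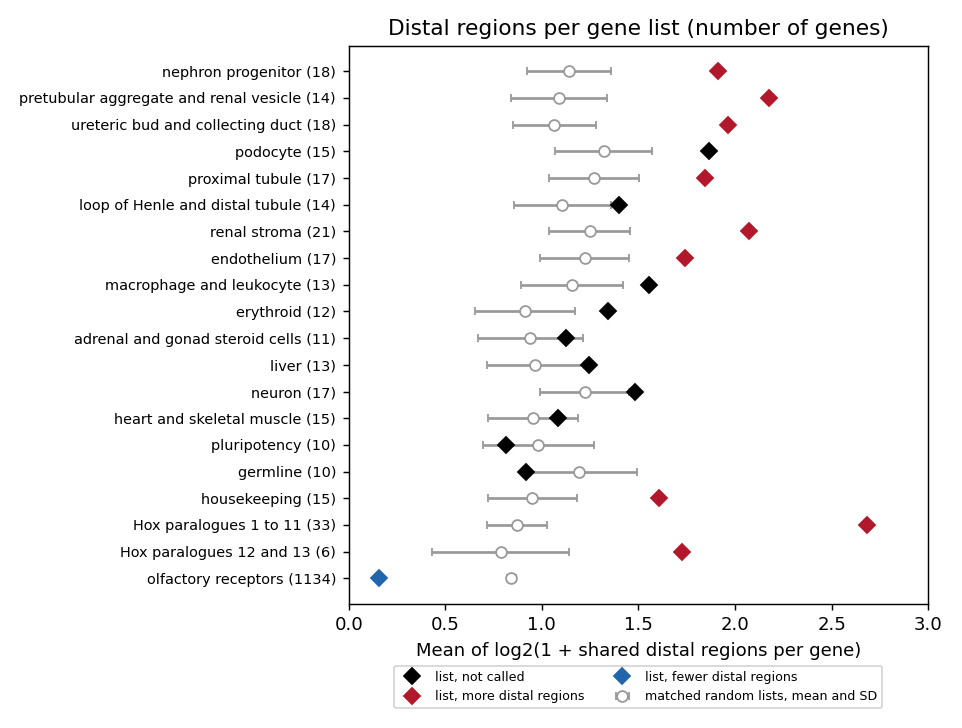
Mean of log2(1 + distal regions of both replicates within the gene body and 50 kb to each side) for each of the 20 lists (x axis; diamonds), beside the mean and SD of 10000 random lists matched on gene length (open circles with bars). Hox paralogues 1 to 11 have the highest mean, 2.68, and olfactory receptors the lowest, 0.16.

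The sequence under distal summits was compared with the flanks of the same peaks for 30 consensus motifs fixed before the data were examined. A motif was called when its share within 50 bp of the summit was at least 1.2 times that in windows 200 bp to each side, in both replicates, and its reversed string did not reach its ratio. Reversed strings of NRF1, YY1 and RFX had no match at summits or flanks and thus no ratio, so these calls rest on the threshold alone. Those of HNF1 and the E-box of TCF21 had no match at summits, and those of CTCF, NFI and PAX2/8 matched at most 0.009% of summits. For these motifs the reversed string is a weak comparison. CTCF, the insulator protein, had the highest ratio, with its consensus CCASYAGRKGGC at 2.24% ± 0.153 of distal summits and 0.120% ± 0.0012 of flanks, an 18.7 ± 1.47-fold difference (SD, n = 2). HNF1 (GTTAATNATTAA), bound by Hnf1a and Hnf1b of renal epithelia, had a ratio of 7.45 ± 0.771, with matches at 38 and 48 summits. PAX2/8 (GTCAYGCNTGA) had 4.67 ± 0.943, with matches at 32 and 38 summits, and the Six1/Six2 motif of nephron progenitors (TCAGGTTTC) 2.46 ± 0.128. HNF4 (CAAAGTCCA), of proximal tubule and liver, had 1.94 ± 0.0212, NFI (TTGGCNNNNNGCCA) 3.07 ± 0.228, TEAD (RCATTCCW) 1.73 ± 0.0132 and AP-1 (TGASTCA) 1.93 ± 0.0735. TEAD was present at 3.39% ± 0.0537 and AP-1 at 3.27% ± 0.179 of distal summits.

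In all, 15 of the 30 motifs were called. The remaining calls were NFY at 1.43 ± 0.103, ETS at 1.39 ± 0.264 and PU.1 at 1.37 ± 0.0649 (SD, n = 2), and the rare E-box of TCF21, NRF1, RFX and YY1, of which YY1 had matches at 6 and 3 summits. With a threshold of 1.5 times, the NFY, ETS and PU.1 calls ended and the other 12 were kept. The ETS ratio in replicate 1, 1.2035, lay just above the threshold of 1.2, and that of its reversed string was 1.1921. In replicate 2 the ETS ratio was 1.5772 and that of its reversed string 1.3859. WT1/EGR (GCGKGGGMG) had a ratio of 2.08 ± 0.183 but was not called, since its reversed string reached 2.26 ± 0.0932, and TFAP2, at 1.96 ± 0.202, and MEIS/PBX, at 1.76 ± 0.205, did not exceed their reversed strings in both replicates. SP/KLF (GGGGCGGGG) had 2.10 ± 0.150 but reads the same reversed, so it could not be called under this rule. GATA, FOX, HOX9-13, SOX, RUNX, MEF2 and POU octamer motifs had ratios from 0.775 ± 0.0899 to 1.16 ± 0.0831 and were not called. Except for SOX (reversed 1.03), each still stood above its reversed string, whose ratio ran from 0.251 for the POU octamer to 0.621 for RUNX. These motifs thus missed the threshold of 1.2 against flanks, which does not show that they are absent from distal summits. At IDR thresholded peaks the HNF1, RFX, YY1, NFI and PU.1 calls ended. HNF1 (8.0, from replicate 2) and RFX had no match in the flanks of 1 or both replicates and so no ratio there, YY1 and NFI had mean ratios of 2.5 and 2.76, and PU.1 fell to 1.17. PAX2/8 kept its call there with a ratio of 16.7, and MEIS/PBX had 1.08. At promoter peaks those for HNF4, PAX2/8 and YY1 ended, and the Six1/Six2 motif (0.845), TEAD (0.984) and the E-box of TCF21 (0.873) fell below 1. NFY (5.26), ETS (5.22), NRF1 (7.74) and SP/KLF (3.73) had higher ratios at promoter peaks than at distal peaks, and CTCF (8.91), HOX9-13 (0.520) and TCF/LEF (0.695) lower ones. YY1 had a ratio of 0.667 within 25 bp of distal summits and 7.5 with flanks 500 bp away, where NFI had 4.85, and NRF1 had 2.17 without replicate 2. Other motifs gained calls, which were WT1/EGR and GRHL within 25 bp, WT1/EGR, FOX, GRHL and MEIS/PBX with flanks 500 bp away, and TFAP2, FOX, GRHL and the NEUROD E-box at IDR thresholded peaks. At promoter peaks TFAP2, MEIS/PBX, the POU octamer and MEF2 did so. GRHL and the NEUROD E-box gained a call without replicate 1, and TFAP2, FOX, TCF/LEF and MEIS/PBX without replicate 2. Ratios were not tested across samples, and a consensus string misses weaker sites.

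**Figure D5:**
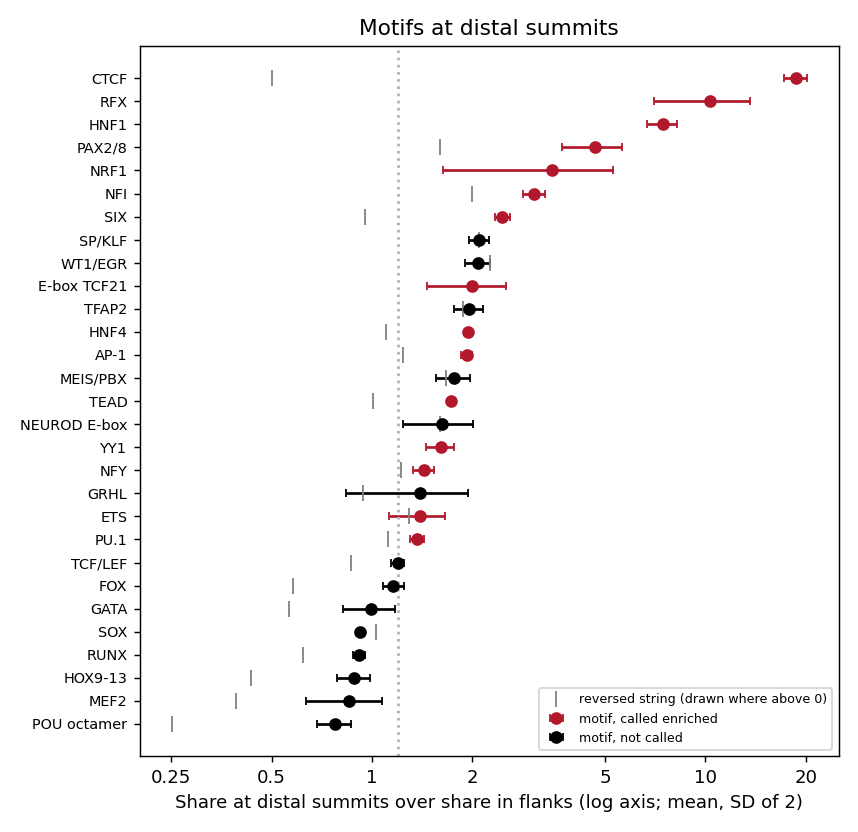
Ratio of the share of distal summits with a motif to the share of flanks (x axis, log scale; points are the mean and bars the SD of 2 replicates) for each motif with a ratio (y axis), red where called enriched. Grey ticks give the ratio of the reversed string, the dotted line marks 1.2, and CTCF has the highest ratio, 18.7.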

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

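The patterns below had been seen before their tests were set, and each test was set before its own result was seen. The test on the 10 highest regions was first set for the highest interval alone, and was widened after the regions had been listed but before their sequences were searched. No biological explanation was tested for any of these patterns, since the design has 1 group. The full ranked lists, which the comparisons above did not use, held intervals that the main lists lacked. On the main chromosomes these were 1677 intervals in replicate 1 and 2078 in replicate 2, and on unplaced sequences 79 in replicate 1 and 97 in replicate 2. Their median −log10 p on the main chromosomes was 4.24 and 4.07, against 12.4 and 11.4 for all intervals, and 13 of the 100 highest by −log10 p were among them in each replicate.

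The interval with the highest −log10 p of both ranked lists, at chromosome 1, 24611586 to 24616160 in replicate 1, was missing from both main lists. Its signal was 3.38 in replicate 1 and 3.46 in replicate 2. Over 100% of its 4575 bp it aligned to the mitochondrial genome, with 99.96% identity in a single alignment. Reads from mitochondrial DNA may therefore account for it, and the match by itself does not exclude open chromatin there.

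The 10 highest regions of the main lists may in part reflect reads from many copies of 1 sequence. Of these, 5, the number set beforehand as the bound, had a mitochondrial match over at least 80% of their length or at least 10 other places in the genome at 90% identity. For 4 of them this was the mitochondrial match, among them the regions nearest Tyrp1 (99.7% of the length) and Nxph1 (89.3%). Of the other 5, the region nearest Galc matched over 74.6% and that nearest Abcb11 over 48.3% of its length. Those nearest Pak3, Frmd4a and Hic2 had no mitochondrial match. They had no other place on the assembled chromosomes in a single alignment at 90% identity over 80% of their length. Shorter copies and copies on unplaced sequences were not counted, and what raised the signal of these regions stays open.

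Regions called in 1 replicate only, 10526 in replicate 1 and 20033 in replicate 2, had a median signal of 3.29 against 4.36 for all peaks of replicate 1 and 3.16 against 4.11 for replicate 2. Of them, 44.4% had a call in the other replicate's ranked list or lay in the lowest quintile of their own, 48.4% in replicate 1 and 42.4% in replicate 2. This was below the bound of 50% set beforehand, but the ranked lists are little longer than the main lists, and only 1.76% and 1.12% of the regions had a call there. The test therefore had little room, and whether the calling threshold at weak sites accounts for these regions stays open. In the lower 3 quintiles lay 96.2% and 93.8% of these regions, a count made after the result was seen, and sequencing depth, which is unknown, may contribute.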

How the results depend on the processing

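Most alternatives were set before the data were examined. The basic annotation set, matching on CpG content and number of starts, regions away from starts of all annotated genes, runs of neighbouring Hox genes, and peaks per replicate without a replicate were chosen after seeing the data. Direction and side of the threshold were the same for overlap (65.7% to 82.7%) and promoter shares (27.3% to 61.1%) under all alternatives. Without a replicate the promoter share was 29.2% to 33.0%. Overlap and rank correlation have no value without a replicate, since both are needed. Peaks per replicate were 53286 to 62602 without a replicate and moved to 19534.5 with IDR thresholded peaks and to 104896.5 with each deposited line counted, by construction. Rank correlation moved from 0.860 to 0.910 with IDR thresholded peaks, 0.837 without the top 5% and 0.897 as Pearson's r of log2 signal. In the authors' pairing of the true replicates it was 0.690. That value is for −log10 p over unmerged lines of the pooled ranked list, so both the measure and the set of peaks differ. The excess of promoter over distal overlap moved from 24.0 to 12.2 percentage points within signal quintiles. It was 18.8 points for peaks of replicate 1 and 29.2 for peaks of replicate 2, but each value used both lists. This excess therefore has no value without a replicate either. With equal numbers of top-ranked peaks, the overlap shares differed little between replicates (74.9% ± 0.798, SD, n = 2), since list length then no longer differed. The count of lists called for distal regions fell from 10 to 5 with IDR thresholded peaks and 4 for the median number of peaks, and was 10 to 12 without a replicate. That for open promoters was 5 to 9, and 6 to 7 without a replicate, but only 2 of the 6 calls were the same with matching on gene length. Called motifs were 12 to 19 against 15, and 17 to 19 without a replicate.

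Some single lists and motifs turned direction with a call before or after. RFX had no ratio with IDR thresholded peaks. With IDR thresholded peaks the open share was 38.1% for renal stroma, 17.6% for endothelium and 16.7% for erythroid genes, and Hox paralogues 12 and 13 had 0 distal regions. Hox paralogues 1 to 11 (81.8% open) were 31.8 percentage points above lists matched on gene length and below those matched on CpG content. YY1 had a ratio of 0.667 within 25 bp. At promoter peaks the Six1/Six2 motif had 0.845, TEAD 0.984 and the E-box of TCF21 0.873, while the POU octamer had 2.0 and MEF2 1.46. The cause of these changes was not tested. Of 200 open promoter values of lists under alternatives, 168 kept their side of the threshold, 11 lost a call and 21 gained one. The difference from the comparison genes changed sign in 31 of them, in 4 with a call lost or gained. Of 161 distal values, 135 kept their side, 19 lost a call and 7 gained one, and 9 changed sign, 1 of them with a call lost. Depth is unknown, so how far it limits weak peaks could not be measured.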

Other observations

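The motif comparison, the chromosome values and the windows below were chosen after the data were seen, and the tRNA and CTCF tests were set after the main results but before their own. Of 15 motifs called at distal summits, 9 were also called at promoter summits, and several had other ratios there. Within 50 bp of promoter summits the NFY consensus CCAATSR was present at 12.8% ± 0.457, against 2.43% ± 0.0412 of flanks, a ratio of 5.26 ± 0.277, and at distal summits the ratio was 1.43 ± 0.103 (SD, n = 2). ETS (ACCGGAAG) had a ratio of 5.22 ± 0.0297 and NRF1 (GCGCATGCGC) 7.74 ± 0.365 at promoters. CTCF had 8.91 ± 0.122 at promoters against 18.7 ± 1.47 at distal summits. The difference between promoter and distal summits was not tested across samples.

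Chromosome X held 6.77 ± 0.666 peaks per Mb and chromosome Y 0.180 ± 0.0230, against 17.96 ± 2.38 on chromosome 14, the lowest autosome, and 29.6 ± 3.19 on chromosome 11, the highest (SD, n = 2). Pools held embryos of both sexes.

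In fixed windows of 200 kb, the densest was at chromosome 2, 30600001 to 30800000, around 1700001O22Rik and Cstad, with 21 distal regions of both replicates, against a mean of 1.88 per window. Windows with 18 regions lay at Rad51b on chromosome 12, Trabd2b on chromosome 4 and Gm20388 on chromosome 8.

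The windows around the Fcgr genes (chromosome 1, 171000001 to 171200000) and a histone gene cluster (chromosome 13, 23400001 to 23600000) held 16 distal regions each. A hypothesis was that these regions lie at tRNA genes, which are not protein-coding starts. Of the 32 regions, 25 (78.1%) lay within 1 kb of a nuclear tRNA gene of the RefSeq annotation. These windows held 25 and 35 tRNA genes. Of the other windows among the 10 densest, that at Haao and Mta3 had 1 region at a tRNA gene and the rest had 0, so tRNA genes do not account for dense windows in general. Across the genome, 184 of 403 nuclear tRNA genes (45.7%) overlapped a region of both replicates. Reads shared between tRNA copies were not examined.

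Another hypothesis was that distal peaks at CTCF sites recur between pools at a given signal. Within signal quintiles, distal peaks with the CTCF consensus were found in the other replicate at a rate −1.23 percentage points from other distal peaks in replicate 1 and 1.10 in replicate 2. These means, below the bound of 5 points set beforehand, cover quintiles that went both ways, such as 7.29 and 8.59 points in the lowest and −8.77 and −1.55 in the third. Without regard to signal the difference was 0.556 and 5.04 points.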
